A study of Homo sapiens with 6 samples.

How the data were processed

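Total RNA from 6 cultures of REH cells was made into TruSeq RNA v2 libraries, 3 with a scramble hairpin and 3 with a hairpin against STAT3, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19, Trimmomatic, Bowtie2, Picard, featureCounts and DESeq2 and the genome build hg38, without saying in which order or with which settings they were used. The annotation, the other versions, the use of strand in counting and the model formula are not given in the sources used here.

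The authors' deposited table has 1 row per gene and compares the 2 groups. Its mean is a normalized signal, the read count divided by a size factor and averaged over the 6 libraries by the authors, as its DESeq2 column name says per the file headers. Its fold change is on the log2 scale, per the file headers, and was computed by the authors. It is a shrunken estimate, since the 1353 genes with 1 read over all libraries have values within 0.0593 of 0. The deposited table also gives the authors' p-value and its adjusted form, per the file headers. Recomputing the Benjamini-Hochberg adjustment over the 12061 genes that have an adjusted p gave the deposited values within 2.87e-07. These genes are called tested here, and their lowest mean is 10.0. Another 5640 genes have a p-value and no adjusted p, all with a mean under 10, 74 have a fold change and no p-value, and 8589 have a mean of 0. Adjusted p-values that are missing were kept missing.

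Groups were taken from the labels before the data were examined, as were the main tests, the 25 gene lists, the other filters and thresholds and the rule for named genes. The plan held a model fit on values per library. As the table has none, the plan's fallback for that case was used, in which a gene is called at the authors' adjusted p under 0.05. The direction of the fold changes was settled from STAT3 alone. The standard error of each fold change was taken as its size divided by the normal quantile of its p-value, and 95% intervals follow from it. As the fold changes are shrunken, this standard error and the intervals are those of values pulled toward 0. For 8 classes of mean, this standard error for small fold changes divided by that for large ones lay between 0.964 and 0.997, near the value of 1 that a Wald test gives. Genes named are STAT3, the 10 highest and 10 lowest fold changes among called genes with a mean of at least 50, up to 3 called members with the smallest adjusted p of each list, and 10 STAT3 targets and JAK-STAT components fixed by name. Genes without a symbol of their own and ZNF286B, a near copy of ZNF286A, were passed over. Some of these genes and 1 of the lists are not reported here.

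Gene lists with at least 5 tested members were tested with cameraPR of limma 3.58.1 in R 4.3.3, on the signed normal statistic of each gene's p, with an inter-gene correlation of 0.01, two-sided, and adjusted over 23 lists by the Benjamini-Hochberg method. The 5 lists written after the data were seen were tested in the same way and adjusted over those 5 alone. An estimated correlation needs values per library, so a correlation of 0.05 was used beside it. Of the alternatives, only the filters and thresholds were set before the data were seen. Alternatives for the lists were the fold change as the statistic, ranks of the signed normal statistic, and medians against 10000 random lists matched on mean count. Others were fold changes less a fit on transcript length, GC content and mean, other filters and thresholds, and genes without a 3′ UTR 7-mer. Because genes are not replicates, the p-value of a list describes this table.

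Depth was read from the means. A mean below 6 is a sum of whole reads, each divided by the size factor of its library and by the number of libraries, so that 6 step sizes explain all of them. This gave exactly 1 set of reads for all 5153 such genes within a tolerance of 4e-09. The libraries recovered in this way carry no label and were not matched to samples or used in any comparison between groups. Gene positions, transcript lengths and 3′ UTRs came from GENCODE 29 on GRCh38, where 23780 of 26364 names matched 1 gene. Length and GC content were known for 89.9% of tested genes and a 3′ UTR of at least 30 bases for 88.7%. Each 7-mer found in at least 100 of the 10697 scanned 3′ UTRs was tested by a rank-sum z of fold change, after a fit on UTR length and GC content, against 100 shuffles of fold changes over genes.

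Tests were tried on simulated data first. Reads were recovered for 289 of 289 simulated genes, and a 7-mer planted in 145 genes with a shift of −0.3 ranked 1. For the lists, the statistic was shuffled over genes and 2 of 23 lists were shifted by 4. Both were called and 0 others. Shuffling removes correlation between genes, so this does not check the inter-gene correlation that was used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.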

Results

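RNA was sequenced from REH, a human cell line of B-cell precursor acute lymphoblastic leukaemia, in 6 libraries. In 3 libraries the cells carried a lentiviral short hairpin RNA against STAT3, a transcription factor that acts downstream of cytokine receptors and JAK kinases, and in the other 3 they carried a scramble hairpin. The replicates came from independent experiments, and puromycin selection lasted 3 days and was followed by removal of dead cells before RNA was extracted. The values analysed here stand in the authors' deposited table of 26364 genes, which holds a mean normalized count over the 6 libraries, a log2 fold change, a p-value and an adjusted p for each gene, and no value per library. Size factors worked out from the lowest means lay between 0.935 and 1.13, so depth differed between libraries by up to 1.21 times, around a mean total of 11485068 normalized counts per library.

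The comparison asked which transcripts differ in REH cells when STAT3 is reduced by a hairpin. Transcripts of DNA replication and mitosis (97 of 99 tested genes) and of cholesterol synthesis (21 of 23) were lower in the shSTAT3 cells, while those of cytosolic ribosomal proteins (53 of 72) were higher, each list with a cameraPR adjusted p of 2.89e-10 or less. STAT3 itself stood at 29.8% of its scramble level in the authors' deposited table (log2 fold change −1.75, 95% interval −1.93 to −1.56, adjusted p = 7.78e-74). The topoisomerase gene TOP2A fell to 29.3% of scramble and the helicase subunit gene MCM6 to 44.1% in the authors' deposited table. HMGCS1, the enzyme that makes HMG-CoA for sterol synthesis, fell to 28.4% of scramble and had the smallest p of all tested genes in the authors' deposited table (adjusted p = 3.02e-160).

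STAT3 lies on chromosome 17 from 42313324 to 42388568 on the minus strand (GRCh38, GENCODE release 29), with a mean of 786 normalized counts in the authors' deposited table. By p-value it ranked 8 among the tested genes, and by fold it ranked 25 among the genes that fell. The table does not state which group is the numerator of its fold changes. A negative value was taken as lower in shSTAT3 because the hairpin targets STAT3, so the fall of STAT3 is not an independent check of the labels.

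Of 12061 tested genes, 5369 (44.5%) passed an adjusted p of 0.05 in the authors' deposited table. The 2565 genes that rose and the 2804 that fell were 47.8% and 52.2% of the calls. Most changes were small, with 61.1% of the calls under 1.5-fold. At least a 2-fold change was reached by 540 genes, 194 higher and 346 lower. The median log2 fold change of all tested genes was 0.0027, and the median standard error implied by fold change and p was 0.12, falling to 0.083 for genes with a mean of 1000 or more and rising to 0.31 for those under 50.

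The largest rise with a mean of at least 50 was that of CYP1A1, the cytochrome enzyme induced through the aryl hydrocarbon receptor, at 7.69-fold in the authors' deposited table (log2 fold change 2.94, 95% interval 2.57 to 3.32, adjusted p = 1.92e-50). CYP1A1 lies on chromosome 15 from 74719542 to 74725610. LILRB2, an inhibitory leukocyte receptor that binds HLA class I, rose 5.20-fold in the authors' deposited table, and CROT, a peroxisomal carnitine acyltransferase, rose 3.44-fold. NEAT1, the long noncoding RNA on which paraspeckles form, rose 3.29-fold and, with a mean of 5150 over all 6 libraries in the authors' deposited table, was the most abundant of the 10. MUC19, a gel-forming mucin gene, NOL4 and the noncoding LINC00324 rose by log2 fold changes of 1.85, 1.69 and 2.11 in the authors' deposited table. The remaining top genes were the antisense transcripts KCNJ2-AS1, SH3BP5-AS1 and TSPEAR-AS1, at 2.43, 2.35 and 1.81 on the log2 scale in the authors' deposited table. These are uncertain, because strand-specific counting is not stated and reads of an overlapping gene could be included. KCNJ2 on the opposite strand, with a mean of 662 against 71.5 for KCNJ2-AS1, also rose in the authors' deposited table (log2 fold change 1.28). SH3BP5 and TSPEAR had means of only 19.2 and 1.90 in the authors' deposited table, against 215 and 125 for their antisense genes, and neither was called.

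C6orf223, an open reading frame of unassigned function on chromosome 6 from 44000580 to 44005958, fell furthest, to 6.97% of scramble in the authors' deposited table (log2 fold change −3.84, 95% interval −4.31 to −3.37, adjusted p = 9.1e-55). HMMR, a spindle and hyaluronan-binding protein, and IFT57, a part of the intraflagellar transport machinery, fell to 21.9% and 21.7% in the authors' deposited table. The neuronal RNA-binding protein gene ELAVL4 and KBTBD13 had log2 fold changes of −2.35 and −2.23 in the authors' deposited table. JPH2, GBA3, GPR146 and HR, the corepressor gene hairless, had log2 fold changes of −1.96, −1.95, −1.90 and −1.87 in the authors' deposited table. The 3′ UTRs of genes at least 2-fold lower, C6orf223, KBTBD13 and TOP2A among them, held the 7-mer TGAAGAA in 29.8% of cases (97 of 326), against 20.4% of other tested genes. No test of this difference is given, because the 7-mer was picked for its tie to lower fold changes in the same table.

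**Figure D1:**
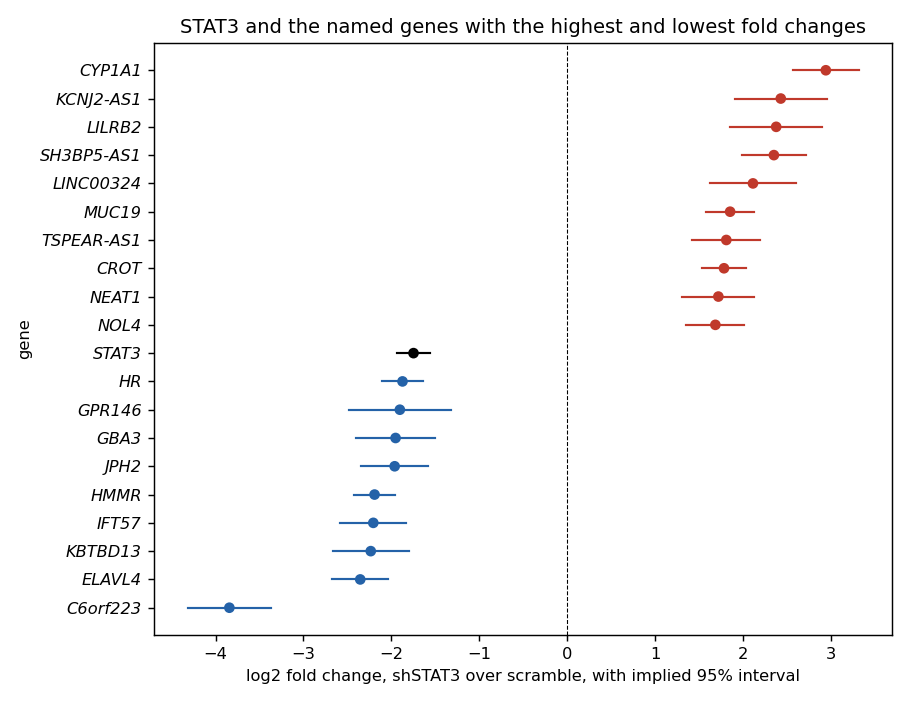
STAT3 and the named genes with the highest and the lowest log2 fold changes (x axis, shSTAT3 over scramble, authors' deposited table) among called genes with a mean of at least 50. Points are fold changes and bars the 95% interval implied by fold change and p. The values run from −3.84 for C6orf223 to 2.94 for CYP1A1, with STAT3 at −1.75, and no interval reaches 0.

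Cell division genes gave the most uniform change of all lists. Of 50 tested genes of DNA replication and the G1/S transition, 49 fell and none rose, with a median log2 fold change of −0.80 (cameraPR adjusted p = 7.45e-39). Adjusted over the list alone, all 50 fell. MCM6 and MCM5, subunits of the replicative helicase, and TYMS, which makes thymidylate, fell to 44.1%, 50.1% and 52.0% of scramble in the authors' deposited table. Of 49 tested mitosis and G2/M genes, 48 fell, also when adjusted over the list alone, with a median of −0.96 (cameraPR adjusted p = 1.71e-49). TOP2A, the topoisomerase that untangles sister chromatids, fell by 1.77 on the log2 scale in the authors' deposited table. HMMR and BIRC5, which encodes survivin of the chromosomal passenger complex, had log2 fold changes of −2.19 and −1.35 in the authors' deposited table. The exception was BUB3, a spindle checkpoint gene outside the rule for named genes, at a log2 fold change of 0.27 in the authors' deposited table.

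Sterol synthesis fell nearly as a whole. Of 23 tested cholesterol synthesis genes, 21 fell and none rose, with a median log2 fold change of −0.85 (cameraPR adjusted p = 9.39e-25); adjusted over the list alone, 21 fell and 1 rose. HMGCS1, on chromosome 5 from 43289395 to 43313512, had a log2 fold change of −1.82 (95% interval −1.95 to −1.69) in the authors' deposited table. INSIG1, which holds SREBP in the endoplasmic reticulum, and FDPS, which makes farnesyl diphosphate, had log2 fold changes of −1.49 and −1.29 in the authors' deposited table. SREBF2, which encodes the main transcription factor of the pathway and was chosen after its value was seen, was at 0.14 with an adjusted p of 0.0574 in the authors' deposited table.

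Genes of the ATF4 and integrated stress response list also fell, 20 of 33 tested against 1 that rose (median −0.39, cameraPR adjusted p = 2.34e-06), and 21 fell when adjusted over the list alone. PHGDH, the first enzyme of serine synthesis, the asparaginyl-tRNA synthetase gene NARS and the neutral amino acid transporter SLC1A4 had log2 fold changes of −1.21, −0.85 and −1.05 in the authors' deposited table.

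Cytosolic ribosomal protein genes rose in 53 of 72 tested cases and fell in 4, by a median log2 fold change of 0.29 (cameraPR adjusted p = 2.89e-10). Adjusted over the list alone, 59 rose and 4 fell. The list also passed, with a larger adjusted p, with the fold change as the statistic (0.0021), with length and GC content removed (0.00943) and with a correlation of 0.05 (0.000315). RPL34 and RPL11 rose by 0.57 and 0.49 on the log2 scale, and RPL23A fell by 0.82, in the authors' deposited table. The other members that fell, named after their values were seen, were RPL17, RPL22 and RPL3, at −0.85, −0.49 and −0.37 in the authors' deposited table. Ribosomal protein genes have many processed pseudogenes, so their counts depend on how shared reads were assigned.

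Of 32 tested p53 targets, 18 rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 0.24 (cameraPR adjusted p = 0.00982). With an inter-gene correlation of 0.05 in place of 0.01 the call was lost (adjusted p = 0.0914). ZMAT3, an RNA-binding p53 target, and the exonuclease gene AEN rose by 0.63 and 0.57 on the log2 scale in the authors' deposited table. PMAIP1, which encodes the BH3-only protein NOXA, fell by 0.92 in the authors' deposited table.

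Mature B-cell and plasma cell genes moved both ways, with 10 of 22 tested higher and 6 lower, or 11 and 7 adjusted over the list alone (median 0.34, cameraPR adjusted p = 0.0116). This call was lost with a correlation of 0.05 (adjusted p = 0.0914), with the fold change as the statistic (0.106), with ranks (0.103) and with length and GC content removed (0.0893). HLA-DPB1 and HLA-DPA1, the chains of an HLA class II molecule, rose by 0.91 and 0.60 on the log2 scale in the authors' deposited table. XBP1, a transcription factor of secretory cells, fell by 0.84 in the authors' deposited table.

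Known STAT3 targets fell in 13 of 27 tested cases and rose in 4, also when adjusted over the list alone, with a median log2 fold change of −0.29 (cameraPR adjusted p = 0.00982). The call was lost with a correlation of 0.05 (adjusted p = 0.0914), and 16 of these genes also belong to another list. BIRC5, the anti-apoptotic gene BCL2 and the cyclin gene CCND3 had log2 fold changes of −1.35, −0.89 and −0.66 in the authors' deposited table. PIM1, MCL1 and MYC also fell, at −0.45, −0.29 and −0.28 in the authors' deposited table (adjusted p = 0.00051, 0.000574 and 0.0329). BCL2L1 rose by 0.20 in the authors' deposited table (adjusted p = 0.0351). BCL3 and CCND2 did not pass, at 0.12 and −0.20 in the authors' deposited table (adjusted p = 0.448 and 0.352). SOCS3, the feedback inhibitor of STAT3 signalling, had a mean of 5.11 and a log2 fold change of −0.69 in the authors' deposited table, with a p of 0.0273 and no adjusted p, because its mean lies under that of the tested genes, so it was not called either way.

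**Figure D2:**
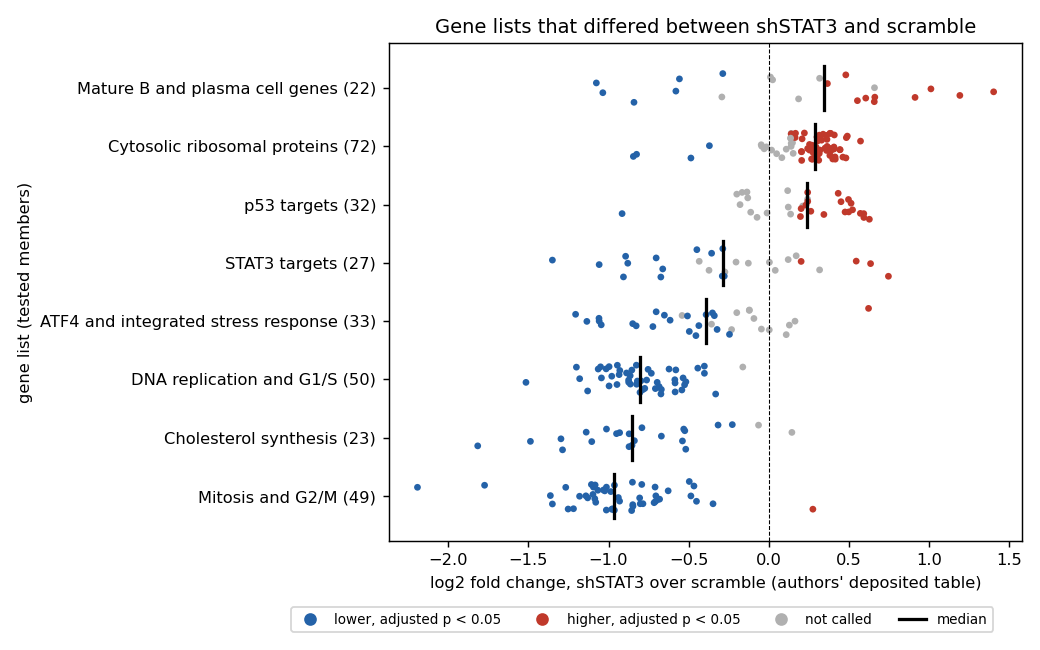
Log2 fold change (x axis, shSTAT3 over scramble, authors' deposited table) of each tested member of the 8 gene lists past the threshold (y axis, number of tested members in parentheses). Points are genes, blue for called lower, red for called higher and grey for not called, and black bars are medians. The medians run from −0.96 for mitosis and G2/M to 0.34 for mature B and plasma cell genes.

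The list of JAK-STAT components did not pass, with 7 of 33 tested genes higher and 11 lower (cameraPR adjusted p = 0.909). JAK3 and IL2RG, a kinase and the common cytokine receptor chain it binds, rose by 0.53 and 0.42 on the log2 scale, and the interferon receptor gene IFNAR1 fell by 0.59, in the authors' deposited table. STAT5A, a neighbour of STAT3 on chromosome 17, fell by 0.49 in the authors' deposited table (adjusted p = 5.35e-05). STAT5B was at 0.01 in the authors' deposited table (adjusted p = 0.927).

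B-cell precursor genes did not pass as a list, with 4 of 38 tested higher and 14 lower (cameraPR adjusted p = 0.408). The SRC-family kinase gene LYN and the lymphoid transcription factor gene IKZF1 fell, with log2 fold changes of −1.83 and −0.54, and CD79A, a signalling chain of the B-cell receptor, rose by 0.63, in the authors' deposited table. In the BCL2 family and caspases 9 of 30 tested genes rose and 8 fell (cameraPR adjusted p = 0.826), with BCL2 and PMAIP1 as above and CASP8, the initiator caspase of death receptors, higher by 0.65 in the authors' deposited table. Among MYC targets and ribosome biogenesis genes 18 of 51 rose and 11 fell (cameraPR adjusted p = 0.352). The nucleolar genes NCL and TCOF1 and the growth regulator PA2G4 had log2 fold changes of −0.61, −0.75 and −0.60 in the authors' deposited table.

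Interferon-stimulated genes rose in 15 and fell in 11 of 56 tested cases (cameraPR adjusted p = 0.352), with a median slightly below 0 and a mean of 0.04. HERC5, a ligase for ISG15, fell by 0.90 while the secreted glycoprotein gene LGALS3BP and the peptide transporter TAP1 rose by 0.57 and 0.54 on the log2 scale in the authors' deposited table. NF-kB targets rose in 5 and fell in 4 of 26 (cameraPR adjusted p = 0.909, median 0.06, mean −0.03). The genes TNFAIP3, TNFAIP8 and RIPK2 had log2 fold changes of −0.51, −1.43 and −0.93 in the authors' deposited table. Immediate-early genes rose in 3 and fell in 10 of 32 (cameraPR adjusted p = 0.209). The mRNA-decay factor ZFP36L1 and the MAP kinase phosphatases DUSP1 and DUSP6 had log2 fold changes of −0.76, −0.61 and −0.53 in the authors' deposited table. Unfolded protein response genes rose in 11 and fell in 9 of 31 (cameraPR adjusted p = 0.826, with the test upward, a median of −0.08 and a mean just below 0). SYVN1 and SEC31A, of endoplasmic reticulum degradation and export, rose by 0.53 and 0.48 on the log2 scale in the authors' deposited table. Of 16 heat shock protein genes 4 rose and 4 fell (cameraPR adjusted p = 0.575), with HSP90AA1 at −1.23, HSP90AB1 at −0.53 and HSPE1 at 0.55 in the authors' deposited table.

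Glycolysis and hypoxia genes fell in 13 and rose in 1 of 32 tested cases (median −0.36, cameraPR adjusted p = 0.0868). This list passed in 5 of the alternatives, among them the fold change as the statistic (adjusted p = 0.00153), and did not pass at a mean of at least 50 (0.149) or with a correlation of 0.05 (0.303). VEGFA and the collagen prolyl hydroxylase gene P4HA2 fell, with log2 fold changes of −1.06 and −1.77, and the lactate transporter SLC16A1 rose by 0.52, in the authors' deposited table. A further 6 members, ENO1, TPI1, ALDOC, PFKFB4, ADM and BHLHE40, have a negative fold change and no p in the authors' deposited table. Of all 74 genes with a fold change and no p 64 are negative, and for the 23 whose reads could be recovered 432 of 550 reads (78.5%) lay in the same library. Genes with 1 read in that library and none elsewhere, 363 in all, had a positive fold change in 0% of cases, and the list could not be tested without that library. Nuclear-encoded oxidative phosphorylation genes rose in 14 and fell in 2 of 49 (cameraPR adjusted p = 0.140, and 0.0431 with ranks). COX7C rose by 0.86 on the log2 scale, and ATP5C1 and SDHD were at −0.99 and −0.74, in the authors' deposited table. No mitochondrially encoded gene of that list stands in the table.

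Markers of other cell types gave few tested genes. Of 8 tested myeloid markers 1 rose and 2 fell (cameraPR adjusted p = 0.826), with CST3 and CSF1R at −0.75 and −0.81 and ITGAM at 0.33 in the authors' deposited table. Another 8 myeloid markers have a fold change and no p in the authors' deposited table. Reads recovered from the low means placed 57.8% of 180 reads of 11 low-count myeloid markers in that same library, which held 23.9% of all recovered reads and was assigned to no sample. Fibroblast and epithelial markers fell in 3 and rose in 1 of 6 (cameraPR adjusted p = 0.209), with the intermediate filament gene VIM, COL1A1 and PDGFRB at −0.90, −0.75 and −0.27 on the log2 scale in the authors' deposited table. T and NK cell markers rose in 1 of 6 (cameraPR adjusted p = 0.856, median −0.05, mean 0.09), namely LAT at 0.93 in the authors' deposited table. TFR2, at 0.42 in the authors' deposited table, was the only tested erythroid or megakaryocyte marker.

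Over these 25 lists, 23 had at least 5 tested members, and 8 passed, 5 lower and 3 higher. Adjusted over the list alone, counts among lists that did not pass moved by at most 3 genes in a direction. Because no value per library was used, neither the spread within groups nor the weight of any library in these calls was checked.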

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

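The alternative statistics, the correlation of 0.05, the random lists, the length and GC fit and the removal of 7-mer genes were chosen after the data were seen. Requiring at least a 1.5-fold change left 2091 genes, 839 higher and 1252 lower, and at least 2-fold left 540, 194 higher and 346 lower, by the construction of these thresholds; the share of lower genes moved from 52.2% to 59.9% and 64.1%. Without a filter on low means 5075 genes were called, 5085 at a mean of 50 or more, 4107 at an adjusted p of 0.01, and 4273 without genes whose 3′ UTR holds TGAAGAA, 2204 higher and 2069 lower (48.4%); this 7-mer was picked for its tie to lower fold changes in the same table, so its removal lowers that share by construction. The STAT3 fold change of −1.75 is the authors' value and is the same in each setting by construction. It was called in each setting in which it was tested, where only the genes adjusted over changed. With an inter-gene correlation of 0.05, 5 of the 8 lists passed; STAT3 targets, p53 targets and mature B and plasma cell genes, each at an adjusted p of 0.0914, were lost, since a higher correlation widens the null. The count of lists past the threshold was 10 without a filter, with ranks and against random lists, and 8 at a mean of 50 or more, with the fold change and with length and GC content removed, and these held all or 7 of the 8; glycolysis and hypoxia passed without a filter (0.0223), with the fold change (0.00153), with ranks (0.00775) and with length and GC content removed (0.000936), and lay at percentile 0 of the random lists, but did not pass at a mean of 50 or more (0.149) or with a correlation of 0.05 (0.303); the cause was not tested. Of 136 cameraPR values for single lists 123 kept their side of the threshold, 6 became weaker, 7 stronger and 0 reversed. Of 184 values for named genes 183 kept it, and BCL2L1 without a filter did not (adjusted p = 0.0509), because more genes were tested. Here too only the adjustment changed. Many of these genes were picked for a small adjusted p or as called extremes, so most could hardly move.

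No paired analysis was possible because the table gives no values per library. For the same reason other normalizations, DESeq2, limma-voom, other pseudocounts, leaving out replicates, fry, an estimated correlation, principal components and other splits of the 6 samples were not run. Depth limits low genes, with a median implied standard error of 0.31 under a mean of 50, and the 5640 genes under a mean of about 10 have no adjusted p.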

Other observations

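The 5 lists of the next paragraphs, the test of hypoxia genes without a p-value and the test of 7-mers of the same base composition were chosen after the result was seen. The p-values of these lists are therefore no independent support.

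Host genes of small nucleolar RNAs rose in 20 of 23 tested cases and fell in 0, by a median log2 fold change of 0.77 (cameraPR adjusted p = 5.35e-16). GAS5 and ZFAS1, long noncoding hosts that share the terminal oligopyrimidine start of ribosomal protein mRNAs, rose 2.29-fold and 2.04-fold in the authors' deposited table. Lysosomal genes rose in 23 and fell in 2 of 47 (median 0.24, cameraPR adjusted p = 3.15e-06). PSAP, the saposin precursor, and CTSA, a protective carboxypeptidase, rose by 0.90 and 1.10, while the cathepsin gene CTSS fell by 0.90, in the authors' deposited table. Genes of HLA class I presentation rose in 10 and fell in 0 of 15 (median 0.30, cameraPR adjusted p = 7.59e-05), with HLA-C and HLA-B higher by 0.57 and 0.51 in the authors' deposited table.

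Fatty acid synthesis genes fell in 12 and rose in 1 of 17 tested cases, by a median log2 fold change of −0.62 (cameraPR adjusted p = 8.4e-12). ACLY, which makes cytosolic acetyl-CoA, and the desaturase genes FADS2 and FADS1 had log2 fold changes of −1.54, −1.42 and −1.12 in the authors' deposited table. SREBF1, which encodes the lipogenic SREBP, and FASN, the fatty acid synthase gene, were at −1.06 and −0.79 in the authors' deposited table. Genes of homologous recombination and the Fanconi pathway fell in 22 and rose in 0 of 26 (median −0.72, cameraPR adjusted p = 7.58e-12). RBBP8, which starts end resection, and BRCA1 were at −1.60 and −0.85 in the authors' deposited table.

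The fall of the replication and mitosis genes was weighed against off-target repression by the hairpin and against a trend with transcript properties. Members whose 3′ UTR lacks TGAAGAA had a median log2 fold change of −0.851, and 10.1% of members hold it against 20.7% of other genes. This argues against repression of their transcripts through TGAAGAA alone. Seed repression through another site was not tested, because the hairpin's sequence is not known here. After a fit on transcript length, GC content and mean over the other genes, which held 4.62% of the variance, the median residual was −0.812 (quartiles −0.948 and −0.655) against −0.854 before, which argues against that trend as the whole cause. A slower cell cycle after loss of STAT3 remains a hypothesis, and an indirect effect of another target of the hairpin could give the same fall. Ribosomal protein genes exceeded 10 matched neighbours each by a median of 0.202 on the log2 scale (bootstrap interval 0.155 to 0.268). The bootstrap drew from the 72 genes, so its interval describes spread among genes in this table and not among libraries.

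Whether off-target repression through the hairpin's seed accounts for part of the genes that fell stays open. TGAAGAA had the lowest z of 15516 7-mers, −8.80, against −4.75 as the lowest in 100 shuffles. Genes with 0, 1 and more sites were called lower in 22.9%, 31.8% and 36.9% of cases, shares that are not corrected for UTR length or GC content. After the fit their median residuals were 0.054, −0.025 and −0.082. Because the 7-mer was picked in the same table, the gap between genes with and without it restates that choice. The 99 other 7-mers of the same bases that lack the shared core GAAGA reached −4.17 at the lowest, within the shuffles. That value belongs to AAGAATG, which overlaps GAAGAAT. The shuffle limit is the lowest over all 15516 7-mers, a wider bar than 99 7-mers need, so base composition is not excluded. The highest z of any 7-mer, 4.24, also lay within the shuffles. Genes with the 8-mer TGAAGAAA differed from others by a median of −0.117 on the log2 scale after the fit, so the shift per gene is small. The hairpin's sequence is not in the labels. STAT3's own transcript holds neither TGAAGAA nor GAAGAAA, the 7-mers with the lowest z (−8.80 and −8.75), and no AGAAGAA, TTGAAGA or ATGAAGA. Outside its 3′ UTR it holds the overlapping GAAGAAT, ACGAAGA and CGAAGAA (z −5.96, −5.56 and −4.98). It also holds AAGAAAC and AAGAATG, whose z lay within the shuffles. A hairpin strand fully matched to that transcript would have its seed site there, so TGAAGAA and GAAGAAA are not that site. The opposite strand of the hairpin was not checked. A regulator that binds sites such as TGAAGAA cannot be excluded with 1 hairpin.

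The 74 genes with a fold change and no p-value, 64 of them negative, may mark a library with unusual RNA, since DESeq2 leaves out a p where a library has an extreme count. For the 23 with recovered reads, 432 of 550 reads (78.5%) lay in the same library. Glycolysis and hypoxia genes were 6 of the 37 with a mean above the filter (16.2%), against 0.265% of tested genes (Fisher's exact test, two-sided, p = 1.38e-09), but this was tested because these genes had been seen there, and they are too abundant for reads to be recovered, so a hypoxia response in that library stays open. RNA of myeloid cells cannot be told apart from myeloid transcripts of REH. The library held 57.8% of recovered marker reads, between the bounds of 40% and 80% set beforehand, against 23.9% of all recovered reads. Of the reads of T and NK cell, erythroid and fibroblast markers it held 38.6%, 36.0% and 40%. The 57.8% pools unlike members. TYROBP, FCER1G and CSF3R had 26, 22 and 21 reads there and at most 4 in any other library. VCAN, CD163 and FCGR3A had 4, 1 and 0 there, and up to 10, 6 and 1 in another. LYZ, S100A9 and ELANE, with means over the 6 libraries of 16.0, 22.2 and 27.9 in the authors' deposited table, are too abundant for reads to be recovered. Apart from puromycin selection and removal of dead cells, no step of the protocol would take out such cells. No count could be rerun without this library.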
